A study of Caenorhabditis elegans with 4 samples.

How the data were processed

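LIN-39 binding was measured by ChIP-seq in strain OP18 hermaphrodites at the L2 stage. Per the labels, the strain carries the transgene wgIs18 with lin-39 tagged by TY1, EGFP and FLAG, made by bombardment and outcrossed 3 times. Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and quenched in 100 mM Tris. Of the cleared lysate, 10% was kept as input DNA, and the rest was precipitated with anti-GFP antibodies. The 4 samples fell into 2 groups by their labels, LIN-39 ChIP (replicates 1 and 2) and input DNA (replicates 1 and 2). Nothing beyond the replicate numbers in the labels says whether the replicates were separate cultures. Peak lists of both ChIP replicates and a combined list of the series were analysed, and no list of the input samples was used here.

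Per the file headers and the source column, the deposited peaks were called with PeakSeq on genome build WormBase WS220. PeakSeq scores the enrichment of ChIP reads over a control. Each peak has a chromosome, a first and a last position in bp and a p-value column that the authors took from the peak caller. That deposited column was settled as q-values, p-values adjusted by the Benjamini-Hochberg form: in order of peak number the values themselves fell at 886 of 1873 steps in the combined list, 73 of 238 in replicate 1 and 17 of 82 in replicate 2, but multiplied by the peak's number they fell at 0 steps in each list (relative tolerance 1e-09). Sorted p-values would not fall at any step, whereas p-values scaled by the number of tests over the rank can. All values were below 0.001. The aligner, the version of the caller, its threshold and its filters are not given in the sources used here. They also do not say whether the combined list was called on pooled reads, or which control was used. Of the peak numbers, 46 of 1920 were absent from the combined list, 5 of 244 from that of replicate 1 and 1 of 84 from that of replicate 2. The product was equal, within that tolerance, at 749 steps in the combined list, 31 in replicate 1 and 0 in replicate 2, as tied p-values would give. Peaks under 50 bp made up 16.7% of the combined list and were kept. Depth is unknown because the lists give no read counts. The q-value of a peak scores its evidence for enrichment over the control, and the precision of a peak's position or height is not given. Intervals given for shares of peaks are Wilson 95% intervals and cover counting error only.

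Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks were ranked by q-value. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Overlap was tested against 10000 random placements that kept each peak's width and chromosome, within a span that ran to the largest coordinate on that chromosome in the 3 lists (one-sided). Differences in median -log10 q or log2 width were tested with 100000 permutations (two-sided), and Benjamini-Hochberg adjustment covered the 4 such tests. Correlations of -log10 q over shared peaks were tested with permutations, for 3 pairs of lists, and the adjusted values equal the raw ones. Chromosome counts were compared with the share of span and with the share of 19971 protein-coding genes counted in a RefSeq table, by exact binomial tests (two-sided) for the latter, adjusted over 6 chromosomes. That table belongs to a later build than the peaks, so only its gene counts and chromosome names were used. A test against chromosome length was left out because the files give no lengths. The central share of autosomal peaks by midpoint was tested against 50% with an exact binomial test.

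On simulated lists, an overlap of 0% planted in replicate 2 passed the level of 0.05 in 2 of 100 runs, and planted overlaps of 9.64% and 50.6% were found at means of 9.92% and 50.7% and passed in 100 of 100 runs each. These lists were placed by the rule of the overlap test itself, with fewer placements per test, and overlaps were planted as exact copies of replicate 1 peaks. The overlap runs thus check the procedure and do not calibrate the test on real lists. Peaks drawn by length gave a call of chromosome I in 7 of 100 runs, and a doubled weight of chromosome I gave one in 100 of 100. Those runs drew peaks independently and tested the share of span, not of genes. They therefore do not calibrate the chromosome tests reported here. A shift in median of 1 unit of -log10 q was found in 50 of 50 runs, and a shift of 0 in 0 of 50.

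The groups, the main tests, the alternatives listed below and the rule for named regions were fixed before the data were examined. Not in that plan were the tests of width, of -log10 q within each replicate list, of correlations and of the central share of single chromosomes. The binomial test by chromosome was planned against length, with gene number as an alternative expectation. The rule named the 20 combined peaks with the smallest q-values, the 5 strongest peaks present in all 3 lists by replicate 1, and lin-39 and unc-119 as the tagged gene and the marker. As no annotation of build WS220 was used here, peaks were named by coordinates alone. Other regions that the text names were chosen after their values were seen. Alternatives covered the overlap that counts as shared, the stronger 50% of each list, placement within 100 kb, each replicate alone, gene number in place of span and a narrower centre. Planned tests of distance to transcription starts, of fixed gene lists and of motif content were not run, because they need the annotation or sequence of WS220. No column with a measured value was left unused.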

Results

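LIN-39 is a Hox transcription factor of the nematode Caenorhabditis elegans that acts in the mid-body, where it is needed for vulval development and for the fates of midbody neurons. Its genomic binding sites were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in hermaphrodites at the second larval stage, L2. The worms were of strain OP18, which carries the integrated transgene wgIs18 encoding LIN-39 fused to GFP and further tags, with unc-119(+) as the selection marker. Chromatin was precipitated with an antibody to GFP. The series held 4 samples, 2 LIN-39 ChIP replicates and 2 input DNA samples. The authors' peaks were analysed as 3 lists, 1 for each ChIP replicate and 1 combined list for the series. No values of the input samples were used here.

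The combined list held 1874 peaks, the replicate 1 list 239 and the replicate 2 list 83. The combined list was thus 7.84 times as long as that of replicate 1 and 22.6 times as long as that of replicate 2. Combined peaks had a median width of 203 bp (interquartile range 93 to 355) and covered 542952 bp, or 0.543% of the chromosome spans. Peaks of replicate 1 had a median width of 291 bp (162 to 402.5) and covered 110563 bp, and those of replicate 2 a median width of 450 bp (310 to 554.5) and covered 58349 bp. The smallest q-value was 1.73e-165 in the combined list, 9.49e-47 in replicate 1 and 3.75e-24 in replicate 2. The files hold no read counts, so the depth behind each list is unknown. The values used here are peak lists of the ChIP replicates, so no test across samples was made, and every p-value below is over peaks, which are not independent replicates.

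The first question was which regions held the most significant LIN-39 peaks. Strength of a peak refers here and below to its q-value alone, not to the amount of binding. All coordinates are of genome build WormBase WS220. The 20 combined peaks with the smallest q-values were found in both replicate lists without exception. Of these, 9 lay on chromosome X, 4 on I, 3 on III, 3 on IV, 1 on V and 0 on II. The strongest was III:7518972-7549765, with q = 1.73e-165 in the combined list and rank 1 in both replicates. It was followed by I:1836207-1838613 (q = 2.74e-35), V:4506679-4508544 (q = 1.07e-34), I:9962174-9963137 (q = 9.08e-34) and X:16929333-16931827 (q = 2.01e-33). The next 5 were X:13700438-13701091 (q = 4.49e-32), IV:14032486-14034462 (q = 4.07e-30), X:14525419-14526171 (q = 5.18e-29), IV:13695535-13696372 (q = 1.17e-28) and I:4699198-4699838 (q = 8.04e-27). The remaining 10 had q-values between 1.95e-26 and 1.26e-19. They were X:11093831-11094355, X:8036013-8036789, X:2996420-2997428, III:8873985-8874667, I:4171981-4172567, IV:13699260-13699897, X:12690267-12690683, X:9465498-9466075, X:14487260-14487633 and III:7550875-7554946. The 2 peaks on IV at 13695535 and 13699260 were neighbours, each found in both replicates.

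Ordered by replicate 1 instead, the 5 strongest peaks present in all 3 lists began with the same interval on chromosome III. The next were X:2996875-2997421 (q = 1.52e-18), X:11093837-11094349 (q = 5.53e-18), X:13700493-13701051 (q = 1.33e-17) and IV:13695616-13696363 (q = 4.92e-17). The region I:1836207-1838613, second in the combined list, ranked 44 in replicate 1 (q = 6.27e-06) and 25 in replicate 2 (q = 1.20e-05). No gene is named for these peaks, because no annotation of build WS220 was used here.

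The strongest peak stood apart in width. The interval III:7518972-7549765 spanned 30794 bp in the combined list, 7.56 times the width of the next widest combined peak, its neighbour III:7550875-7554946 (4072 bp), and 9.47 times that of the widest away from this locus, I:227647-230898 (3252 bp). Replicate 1 had a peak at III:7518995-7549762 (30768 bp), whose ends lay 23 and 3 bp inside the combined interval. Replicate 2 had a peak at III:7522622-7538777 (16156 bp), which covered 52.5% of the interval and stopped 10988 bp short of its right end. The interval made up 27.8% of all bases in the replicate 1 list, 27.7% in that of replicate 2 and 5.67% in the combined list. That neighbour (q = 1.26e-19) followed after a gap of 1109 bp. It was found in replicate 1 at III:7550913-7554908 (q = 1.67e-05) and in replicate 2 at III:7550875-7554880 (q = 0.000204). The tagged gene lin-39 and the marker gene unc-119, which is required for nervous system development, both lie on chromosome III. Their positions relative to these peaks were not determined, since the gene table used here belongs to another build.

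**Figure D1:**
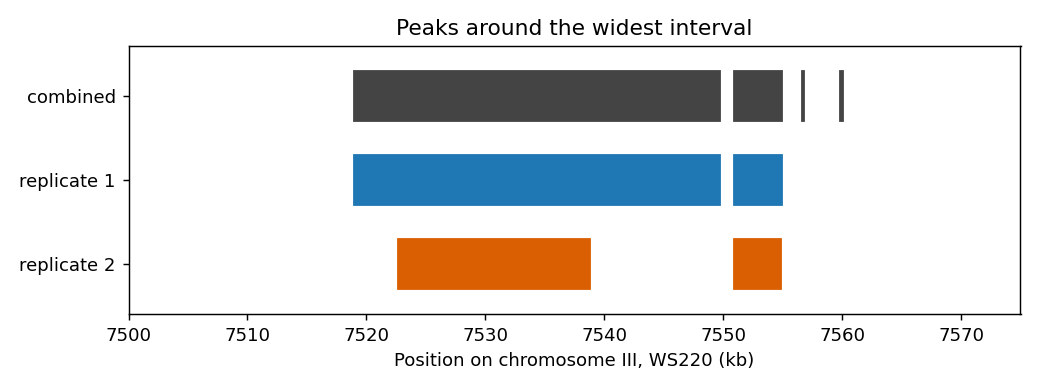
Peaks of the combined list and of both replicates around the widest interval, drawn to scale against position on chromosome III in kb (WS220), with 1 bar per peak. The combined and replicate 1 peaks span 30794 and 30768 bp, whereas the replicate 2 peak spans 16156 bp.

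The second question was how far the replicates called the same regions. Of the 83 replicate 2 peaks, 60 overlapped a replicate 1 peak by at least 1 bp (72.3%, Wilson 95% interval 61.8 to 80.8%). Random placement of the peaks on their own chromosomes gave a mean of 0.232 overlaps and at most 3 (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). In the other direction, 60 of 239 replicate 1 peaks (25.1%, 20.0 to 31.0%) overlapped a replicate 2 peak. Shared peaks were the stronger ones in both lists. In replicate 1 their median -log10 q was 5.43, against 3.52 for the other 179 (difference 1.91, two-sided permutation p = 1e-05, adjusted p = 2e-05 over 4 tests). In replicate 2 it was 4.50, against 3.39 for the other 23 (difference 1.11, permutation p = 0.006, adjusted p = 0.006). The -log10 q values of the 60 shared peaks rose together (Spearman rho 0.734, Pearson r 0.882, permutation p = 0.0001 for rho, a relation across peaks within 1 pair of samples). The value of r includes the wide interval on chromosome III, which lay far from the other peaks, and r was not computed without it. In replicate 1 that interval had q = 9.49e-47 and the next peak 1.52e-18, and in replicate 2 they had 3.75e-24 and 3.53e-12.

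Regions found in a single replicate were also listed. The strongest replicate 1 peak without a replicate 2 partner was II:6838187-6838534 (q = 6.69e-09, rank 19), followed by II:10563313-10563632 (q = 2.10e-07) and IV:10341714-10342681 (q = 2.17e-07). The strongest replicate 2 peaks without a replicate 1 partner were X:11030963-11031627 (q = 1.23e-05), III:4281970-4282599 (q = 2.13e-05) and X:4961883-4962554 (q = 2.98e-05). These single-replicate regions were chosen after their values were seen. Absence from a list means that no peak passed the authors' threshold there, and a region missing from replicate 2 was not shown to differ from replicate 1.

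The combined list was then compared with each replicate. It contained 213 of the 239 replicate 1 peaks (89.1%, 84.5 to 92.5%) and 82 of the 83 replicate 2 peaks (98.8%, 93.5 to 99.8%). Random placement gave means of 4.16 and 1.65 peaks and maxima of 14 and 8 (one-sided permutation p = 0.0001 for each, the smallest possible). The 26 replicate 1 peaks absent from the combined list were narrow, with a median width of 28.5 bp against 308 bp for those present. The single replicate 2 peak absent from it was I:7627960-7628041 (82 bp, q = 0.00057). Scores rose together between the combined list and replicate 1 (rho 0.683 over 213 peaks, r 0.883) and between the combined list and replicate 2 (rho 0.743 over 82 peaks, r 0.861), each with permutation p = 0.0001 for rho. Both values of r include the wide interval on chromosome III, far stronger than any other peak, and were not computed without it. The combined list comes from the same series, so these overlaps are not independent evidence for a peak.

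Of the 1874 combined peaks, 59 (3.15%) were in both replicates, 152 (8.11%) in replicate 1 only, 22 (1.17%) in replicate 2 only and 1641 (87.6%) in neither. The 59 peaks in both had a median -log10 q of 14.2 and a median width of 525 bp. Peaks in replicate 1 only had medians of 6.44 and 338.5 bp, and those in replicate 2 only 6.93 and 434.5 bp. The 1641 peaks in neither had medians of 3.81 and 189 bp. The 59 peaks exceeded the other 1815 by 10.3 in median -log10 q (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 2e-05) and by 1.40 in median log2 width (p = 2e-05, adjusted p = 2.7e-05). All lists come from the same series, so a peak that passed in both replicates would tend to score higher in the combined list. These differences describe the lists and are not independent evidence.

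Recurrence fell steeply with rank in the combined list. All 20 peaks of ranks 1 to 20 were in both replicates (100%, 83.9 to 100%). Of ranks 21 to 100, 58 of 80 were in replicate 1 (72.5%, 61.9 to 81.1%) and 35 in replicate 2 (43.8%, 33.4 to 54.7%), and 65 were in at least 1. For ranks 101 to 500 the shares were 26.0% and 6.25%, and for ranks 501 to 1000 they were 3.80% and 0%. Among the last 874 peaks, 10 (1.14%) were in replicate 1 and 1 (0.114%) in replicate 2. The strongest combined peaks in neither replicate all lay on chromosome I, namely I:7711673-7713037 (q = 1.33e-13, rank 39), I:171068-173936 (q = 5.69e-13, rank 43) and I:2292720-2295243 (q = 1.27e-12, rank 46). All 15 peaks among the 100 strongest that neither replicate listed were on chromosome I.

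**Figure D2:**
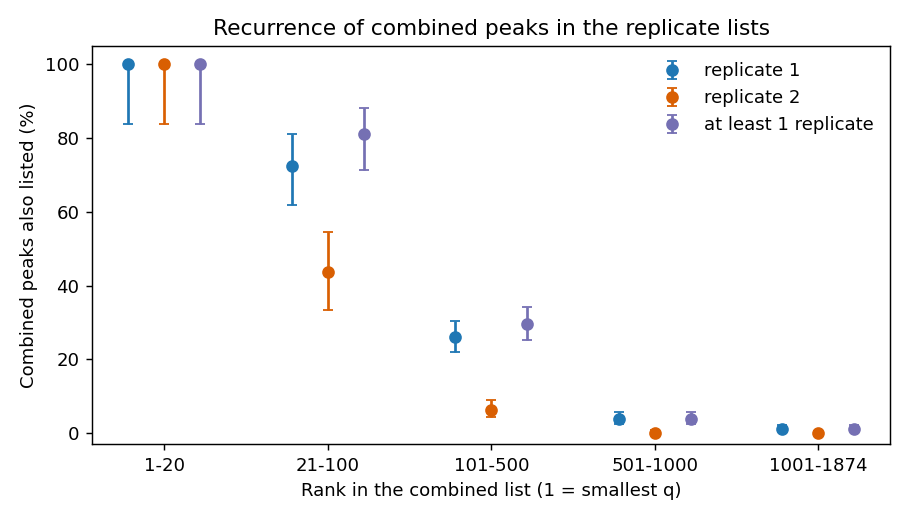
Share of combined peaks also listed in replicate 1, in replicate 2 or in at least 1 of them (%, vertical axis) by rank in the combined list (horizontal axis), with Wilson 95% intervals as bars. All 20 peaks of the first class recur in both replicates, and 1.26% of the last class recur in at least 1.

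The third question was how the peaks were spread over the 6 chromosomes. Chromosome I carried 785 of the 1874 combined peaks (41.9%, 39.7 to 44.1%), 2.80 times the number its span would give (2.65 to 2.95) and 2.91 times the number its protein-coding genes would give (2.75 to 3.06; exact binomial test against gene number, two-sided, adjusted p = 2.66e-182 over 6 chromosomes). Its density was 52.4 peaks per Mb, against 10.5 on V and 17.8 on X. The other 4 autosomes held fewer peaks than their spans would give, with ratios of 0.675 on II, 0.651 on III, 0.596 on IV and 0.560 on V. In single replicates the ratio on III was 0.334 (0.188 to 0.585) in replicate 1 and 0.875 (0.485 to 1.51) in replicate 2, and that on IV was 0.671 and 0.897. The interval of II included 1 in both replicates, and those of III and IV included 1 in replicate 2. Among the chromosomes other than I, a choice made after the counts were seen, the combined ratios were 0.988 on II, 0.952 on III, 0.872 on IV and 0.819 on V. Chromosome I was also above its span in replicate 1 (76 peaks, 31.8%, ratio 2.12, 1.75 to 2.54) and in replicate 2 (20 peaks, 24.1%, ratio 1.61, 1.08 to 2.29). Against gene number, the adjusted p was 5.03e-11 in replicate 1 and 0.0359 in replicate 2.

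Chromosome X was above its span in both replicates but not in the combined list. It carried 63 of 239 peaks in replicate 1 (26.4%, ratio to span 1.49, 1.20 to 1.83) and 24 of 83 in replicate 2 (28.9%, ratio 1.64, 1.15 to 2.23). In the combined list it carried 314 peaks (16.8%, ratio 0.948, 0.856 to 1.05). Against gene number its ratio was 1.93 in replicate 1, 2.12 in replicate 2 and 1.23 in the combined list (exact binomial test, adjusted p = 6.66e-07, 0.00169 and 0.000163). When chromosome I was left out, a comparison chosen after the counts were seen, X held 28.8% of the other 1089 combined peaks, 1.39 times its share of the span (1.26 to 1.52). The corresponding ratios were 1.86 (1.52 to 2.23) in replicate 1 and 1.83 (1.30 to 2.43) in replicate 2. Of the X peaks in the combined list, 19.7% (15.7 to 24.5%) were in at least 1 replicate, against 9.30% (7.46 to 11.5%) of those on chromosome I and 7.74% (4.58 to 12.8%) of those on III. The shares on II, IV and V were 13.5%, 14.4% and 14.2%. Spans are the largest coordinate found on each chromosome in the lists, so the ratios to span were given without a test.

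**Figure D3:**
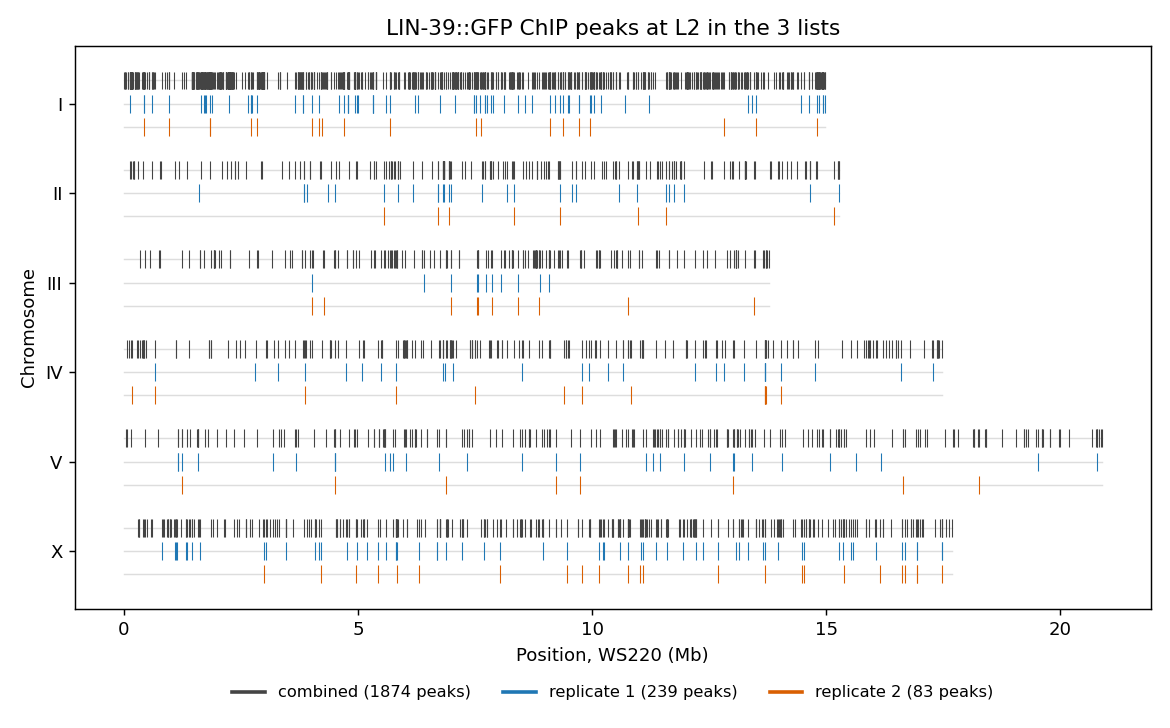
Position of every peak along the 6 chromosomes (Mb, WS220), 1 tick per peak, with the combined list on top of each chromosome and replicates 1 and 2 below it. Chromosome I carries 785 of the 1874 combined peaks, 76 of the 239 replicate 1 peaks and 20 of the 83 replicate 2 peaks.

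**Figure D4:**
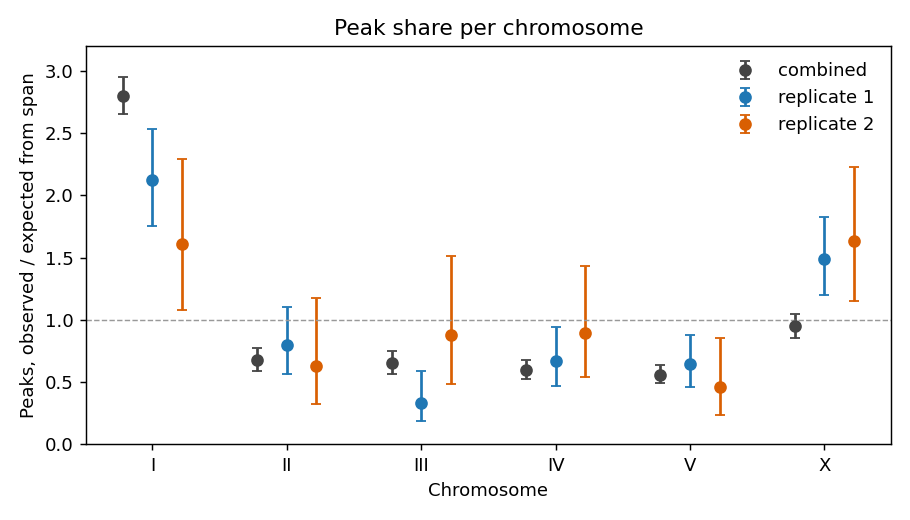
Observed number of peaks over the number expected from the chromosome's span (vertical axis) for each chromosome and list, with Wilson 95% intervals as bars and a dashed line at 1. Chromosome I lies above 1 in all 3 lists (2.80, 2.12 and 1.61), and X lies above 1 in both replicates (1.49 and 1.64) and at 0.948 in the combined list.

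For the 59 combined peaks present in both replicates, scores were also compared between lists, a comparison added after the chromosome counts were seen. The combined -log10 q was divided by the sum of both replicates' values for the same peak. The median ratio was 1.59 on chromosome I (15 peaks, 1.28 to 3.41), 1.47 on III (7 peaks, 1.19 to 2.37) and 1.08 on II, IV, V and X together (37 peaks, 0.892 to 1.72). Chromosome I exceeded the latter 4 by 0.511 (permutation p = 1e-05, the smallest possible) and III exceeded them by 0.385 (permutation p = 0.00043). The highest ratio, 3.41, was that of I:1836207-1838613.

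**Figure D5:**
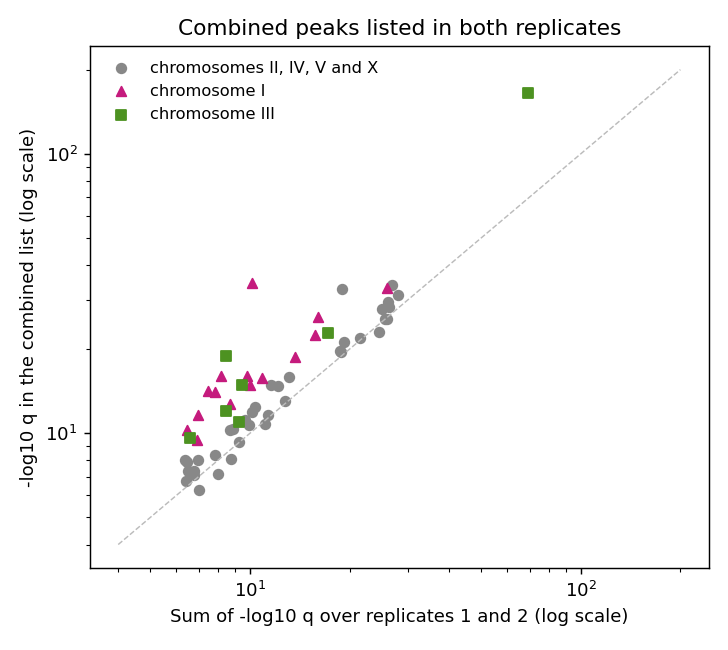
Combined -log10 q (vertical axis, log scale) against the sum of -log10 q over both replicates (horizontal axis, log scale) for the 59 combined peaks in both replicates, with 1 point per peak and a dashed line where the values are equal. All 15 peaks of chromosome I (triangles) and all 7 of III (squares) lie above the line, at median ratios of 1.59 and 1.47.

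The position of peaks within the autosomes, which have gene-dense centres and repeat-rich arms, was examined last. In the combined list 825 of 1560 autosomal peaks lay in the middle 50% by length (52.9%, 50.4 to 55.4%, exact binomial test against 50%, two-sided, p = 0.0242). The central share was highest on III (62.5%, exact adjusted p = 0.00858 over 6 chromosomes), V (60.3%, adjusted p = 0.00858) and II (59.1%, adjusted p = 0.0284). It was 55.9% on IV (exact adjusted p = 0.138), 52.2% on X (adjusted p = 0.463) and 46.5% on I (43.0 to 50.0%, adjusted p = 0.0808). On chromosome I the replicates lay on the other side of 50%, at 63.2% (48 of 76, 51.9 to 73.1%, exact adjusted p = 0.0573) in replicate 1 and 55% (34.2 to 74.2%, exact adjusted p = 1) in replicate 2. In replicate 1, 116 of 176 autosomal peaks were central (65.9%, 58.6 to 72.5%, exact p = 2.93e-05), including all 11 on chromosome III. In replicate 2 the count was 34 of 59 (57.6%, 44.9 to 69.4%, exact p = 0.298), so the call was not reached in that list alone. With chromosome I left out, a choice made after the counts were seen, 460 of 775 autosomal combined peaks were central (59.4%, 55.9 to 62.8%, exact p = 2.1e-07).

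Combined peaks were also examined for close neighbours. After the lists were seen, peaks within 2 kb of the next were counted, and 239 such neighbours were found. In 1000 random placements on the same chromosomes the mean was 121 and the maximum 155 (one-sided permutation p = 0.001, the smallest possible). The placements ran over whole chromosomes and did not keep regional density, which was uneven on chromosome I. Uneven density alone could give more neighbours than these placements, so the test cannot show closeness at the scale of 2 kb. Placement within a local window was not run for this count. Joined at that distance, the peaks formed 1635 separate regions, of which 1468 were single peaks, 126 were pairs and 41 held 3 or more. The region with the most peaks was I:2231038-2247152, with 9 peaks over 16115 bp and a smallest q of 1.33e-12. It was followed by I:145432-157061 with 7 peaks and by I:7708370-7715970 and I:160492-167986 with 6 each. Outside chromosome I, the largest were X:6740538-6745749 and II:6821055-6827698, with 5 peaks each. Of the 10 regions with most peaks, ties ordered by q, 8 lay on chromosome I, and I:1833851-1842238 held the second strongest peak of the combined list.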

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

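Leaving out chromosome I, taking the 100 strongest peaks and counting peaks within 2 kb once were alternatives chosen after the data were seen. The overlap of the lists (9 alternatives, 71.1 to 85.4% between replicates, 79.5 to 84.5% for replicate 1 and 91.6 to 97.6% for replicate 2 in the combined list) stayed past its test throughout, as did the higher significance of recurring peaks (differences of 3.72 and 10.6). Neither the overlap with the combined list nor that higher significance is independent evidence, since the lists come from the same series. The excess on chromosome I stayed above 1 in each alternative run. It was 3.04 in the stronger 50% of the list, 3.74 among the 100 strongest peaks, 2.53 with neighbouring peaks counted once and 1.61 to 2.12 in single replicates. The ratio of chromosome X, 0.948 in the combined list, was 1.49 to 1.64 in single replicates, 1.23 by gene number, 1.13 among the 100 strongest and 1.39 among the chromosomes other than I. By construction, the value by gene number differs through the expected share alone (13.7% of genes, 17.7% of span) and the last through removal of the crowded chromosome, and the cause of the others was not tested. The central share over that expected, 1.06 in the combined list, was 1.15 to 1.32 in single replicates, and in replicate 2 alone, with 59 autosomal peaks, it no longer passed (exact p = 0.298). Of all 57 alternatives, 30 left the result in place, 26 moved it (chromosome ratios only) and 1 weakened it. A chromosome ratio was in place when it stayed within the Wilson interval of its main value. The alternative's own interval was not used, so a ratio counted as moved can have an interval that includes the main value. On III, for example, replicate 2 gave 0.875 (0.485 to 1.51), against a main value of 0.651. For the other results, in place meant the same direction with the test still passed, and the value itself could change. The difference in median -log10 q, for example, went from 10.3 to 3.72.

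No paired analysis was possible because no values of the input samples were used here and each result compares peak lists, not groups of samples. Tests of transcription starts, gene lists and motif content, with their alternative settings, were not run, since they need the annotation or sequence of build WS220. Depth is unknown, so a peak missing from a replicate's list was not shown to be absent there.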

Other observations

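The tests of peak width against strength, of the scores of chromosomes I and III in the combined list, of replicate 2 coverage and of the 20 strongest peaks were chosen after the results were seen. The comparison with gene number was planned, but its bound was set after its value was seen. The other tests in this part were written down before their results.

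The combined list gained peaks unevenly. Relative to replicate 1, it held 15.3 times as many peaks on chromosome III, 10.3 times on I, 6.66 to 6.96 times on II, IV and V and 4.98 times on X. Relative to replicate 2 the order differed, with 39.2 times as many on I, 27.4 on V, 24.1 on II, 16.8 on III, 15 on IV and 13.1 on X. Chromosome III held only 11 and 10 peaks in the replicates, so its gain is imprecise. Chromosome I held 4 of the 20 strongest combined peaks, 52 of the 80 peaks of ranks 21 to 100, 48.2% of ranks 101 to 500 and 37.8% of ranks 1001 to 1874. Its peaks were spread over the whole chromosome but unevenly, with 28 to 97 peaks in each of its 15 bins of 1 Mb. No bin on another chromosome held more than 25.

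The peak on chromosome III was 7.56 times as wide as the widest of the other 19 strongest peaks. Whether strength alone accounts for this cannot be told, since its -log10 q was 165 and the next strongest peak had 34.6, so no peak of like strength was there for comparison. Extra copies of the transgene insert, which carries lin-39, are a candidate explanation that these lists also leave open. Replicate 2 had 0 peaks in the last 10 kb of the interval, which a bound set in advance counted against extra copies. That bound was too strict to decide: the replicate 2 peak covered 52.5% of the interval. Replicate 2 covered as little of 3 of the other 19 strongest peaks, down to 39.5% at V:4506679-4508544. The median over those 19 was 83.2%, so the coverage of the interval was in the lower part of their range. No biological explanation, such as dense LIN-39 binding over this interval, was tested.

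The excess on chromosome I could have several technical sources. A duplicated or contaminated stretch as the source of the whole excess is argued against by the spread of the peaks. Each of the 15 bins of 1 Mb held at least 28 peaks, and no bin on another chromosome held more than 25. The 3 fullest bins held 31.5% of the peaks of chromosome I (28.3 to 34.8%), within the limit set in advance. That limit cannot exclude a stretch that supplied a part of the excess, which stays open. Gene number is argued against by a lower bound of 2.75 for the ratio. A looser threshold for weak peaks stays open: the share of chromosome I in the weaker 50% of the list was 0.684 times that among the 100 strongest, under the bound set in advance, but these ranks rest on the combined scores examined next, and against the 20 strongest peaks it was 1.92 times, with an interval for their share (20%, 8.07 to 41.6%) that includes the 38.3% of the weaker peaks. The median ratio of the combined -log10 q to the replicates' sum was higher on chromosome I than on all others by 0.472 (permutation p = 1e-05, the smallest possible). It was also raised on III, by 0.385 over II, IV, V and X (permutation p = 0.00043). III held fewer peaks than its span would give (0.651), but its ratio was 0.952 among the chromosomes other than I. Its gain over replicate 1, 15.3 times, was the largest, from 11 peaks, whereas its gain over replicate 2, 16.8 times, was not. III thus does not decide for or against a scoring difference as the source. A different scoring of chromosome I in the combined list therefore stays open as a source of a part of the excess. It does not cover the smaller excess in the single replicates (1.61 and 2.12), which are separate lists, and the source of that excess stays open. No biological explanation was tested.

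More reads behind the combined list may account for its length. It held 91.6% of the 322 replicate peaks (88.1 to 94.2%; 89.1% for replicate 1 alone), and 15 of its 100 strongest peaks were in neither replicate, within the limits set in advance, although the interval includes 90%. All 15 lay on chromosome I, where the combined scores were also raised, so the gain there is not set apart from a scoring difference. The lists come from the same series, so a high recovery could arise whatever made the combined list longer and does not single out read number. Read numbers were not used here.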
